A study of Mus musculus with 9 samples.

How the data were processed

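Poly-A RNA was sequenced from natural killer (NK) cells grown from the bone marrow of C57BL/6 mice. Per the labels, marrow cells were kept for 4 days in MEM-α with IL-7 (1 ng/mL), Flt3L (10 ng/mL), SCF (30 ng/mL) and IL-15 (50 ng/mL), and then for another week with IL-15 (50 ng/mL) and IL-2 (20 ng/mL). The series holds 9 libraries in 3 groups of 3. Ctrl cells were untreated, TGFb cells received TGF-β1 at 5 ng/mL for 3 h, and SIS3_TGFb cells received SIS3, an inhibitor of Smad3, at 10 µM for 3 h before TGF-β1 at 5 ng/mL for 3 h. The sample titles of the last group name SIS3 alone, and its treatment text and the series design give TGF-β1 as well. No group received SIS3 without TGF-β1, and a solvent control is not given in the sources used here. Libraries were made from 1 µg RNA and read as 100 bp pairs on a DNBseq instrument. The labels do not say whether the replicates of a group are separate mice or cultures, so the p-values measure only the spread between these libraries.

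The authors deposited one table of expected counts per gene (estimated reads per gene, not scaled for depth). That unit was read from the values: between 10.2% and 11.1% of the values of each library are not whole numbers, and the totals of the libraries differ. The submitters' processing notes name HISAT2, StringTie, Cufflinks, Bowtie2, RSEM and DESeq2 and the builds GRCm38 and mm10. The versions and roles of these tools and the gene annotation are not given in the sources used here. The table holds 16876 genes by Entrez number and symbol, of which 27 are at 0 in every library. It gives no symbol for 15 genes, and the RefSeq gene table for GRCm38.p6 named 0 of these. Positions printed beside gene names come from that RefSeq table. Library totals ran from 15714973 to 16718673 expected counts.

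Expected counts were rounded to whole numbers. Genes were kept by the filterByExpr function of edgeR (minimum count 10, minimum total 15), which left 12212 genes. Libraries were scaled with TMM factors, and all 9 were fitted together with 1 mean per group by the quasi-likelihood functions glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3. The common biological coefficient of variation was 4.5%, with 6 residual and 9.2 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was said to have risen or fallen at an adjusted p below 0.05, with no minimum fold. Values per library are CPM with TMM scaling, given as mean ± SD over 3 libraries. Fold changes are on the log2 scale, given with an SE. That SE is the size of the log2 change divided by the square root of the F statistic of its test.

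Gene lists, groups compared, tests and the rule for naming genes were chosen before the data were examined. Of 44 lists, 41 had at least 3 members tested and were compared with all other genes by camera (limma 3.58.1) with a preset correlation between genes of 0.01. P-values were adjusted over the lists of each comparison, and camera was also run with the correlation estimated from the data. The fry test of limma compared each list with no change instead of with other genes, and lists are said to have passed by camera unless fry is named. The count of members that passed the edgeR test was taken over all genes tested and also adjusted over the list alone. The lists cover TGF-β signalling, NK cell function, metabolism, stress responses, proliferation and markers of cell types. Members were chosen from general knowledge and not from these libraries.

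Named genes are, per comparison, the 8 largest rises and the 8 largest falls among genes past the test with a mean of at least 1 log2 CPM and libraries that do not overlap between the groups, leaving out numbered gene models, Rik symbols and pseudogenes. Further named genes are up to 4 members with the smallest p of each list described and up to 2 that changed the other way, 15 genes fixed by name, and, over the 2 steps, the 8 genes moved back and the 5 moved further with the largest summed change. A gene moved back if it passed the test in TGFb versus Ctrl and also, with the opposite sign, in SIS3_TGFb versus TGFb. Those comparisons share the TGFb libraries, so the count was set beside 20 simulations of unchanged groups. Fold changes against a group whose libraries are all at 0 are given as lower bounds against 3 counts over the group. Ratios with 1 to 3 counts have counting intervals. Bounds and intervals cover counting error only.

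The test was checked on simulated data with known changes. In TGFb versus Ctrl it recovered 56% of genes changed 1.25-fold, 82% at 1.5-fold and 98% at 2-fold, with 10 unchanged genes called, and in SIS3_TGFb versus TGFb 60%, 80% and 96% at the same folds, with 11 unchanged genes called. In simulated data with all 3 groups and 200 genes made to move back, 164 genes were called moved back. That count was taken over all genes, so it may include genes outside the 200. For the lists, the shifted list was called and 0 of 40 unchanged lists were called. Genes were drawn independently there, so that check could not show false calls that come from correlation between genes. Alternatives were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, limma voom, no filter on low counts, a filter of 1 CPM in 3 libraries, the 6 compared libraries alone, replicate number as a block, a log2 change of at least 1, an estimated correlation, and leaving out each library in turn. Chosen after the data were seen were library totals without scaling factors, leaving out TGFb replicate 3 together with SIS3_TGFb replicate 3, the level of macrophage markers as a covariate since SIS3_TGFb replicate 3 was high in them, and a covariance of the steps restricted to genes of at least 4 log2 CPM. The 2 libraries left out together lay farthest from their groups, with a mean chi-square per gene of 5.46 and 5.44 against 2.13 for the other TGFb pair, and of 4.43 and 5 against 1.64 for the other SIS3_TGFb pair. GC content and transcript length were taken from GENCODE M21 transcripts matched through Entrez numbers and were found for 96.6% of the genes tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads of close paralogs (the granzymes Gzmc to Gzmg, the Klra receptors, the Gimap genes) are split by the authors' expected-count model, and how uniquely they map was not tested. Some genes of the fixed lists are not reported here by name.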

Results

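Gene expression was measured by RNA sequencing in mouse bone marrow-derived NK cells that were untreated (Ctrl, n = 3), given TGF-β1 (TGFb, n = 3) or given the Smad3 inhibitor SIS3 before TGF-β1 (SIS3_TGFb, n = 3). TGF-β is a cytokine that restrains NK cells, and Smad3 carries its signal to the nucleus. The Ctrl libraries held 16118249, 16435018 and 16400028 expected counts. The TGFb libraries held 16492031, 16639359 and 15714973, and the SIS3_TGFb libraries 16500985, 16718673 and 16483474. Between 14193 and 14862 genes were above 0 per library, and the 10 most abundant genes took 11.4% to 14% of the counts. The 3 groups lay apart on the first principal component (53.6% of the variance), with Ctrl at -35.3 to -35, TGFb at 5.7 to 9.1 and SIS3_TGFb at 26.2 to 29. TGFb replicate 3 lay apart from the other TGFb libraries on the second (19.2%), at -30.4 against -15.2 and -17.7, and on the third (8.4%), at 20.1 against -14.9 and -15.7.

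Transcripts of NK cells dominated the marker genes in all groups. The 14 NK identity markers summed to 18570 ± 514 CPM in Ctrl, 14030 ± 704 CPM in TGFb and 15390 ± 133 CPM in SIS3_TGFb, of which the killing proteins Gzmb and Prf1 made up 44.3% and 32.8%. Macrophage and monocyte markers, led by Lyz2 (41.8%), summed to 1811 ± 295, 1462 ± 318 and 1582 ± 524 CPM. Dendritic cell markers, led by Cd74, summed to 767 ± 119, 660 ± 138 and 720 ± 217 CPM. Mast cell and basophil markers, led by Kit and Mcpt8, summed to 626 ± 12.8, 606 ± 36.5 and 618 ± 52.2 CPM. Neutrophil markers came to 293 ± 18.6, 252 ± 6.5 and 235 ± 6.52 CPM, nearly all from Ctsg (94%). T cell markers came to 1797 ± 65.7, 1877 ± 74.9 and 1539 ± 48.4 CPM, mostly from Thy1 (84.4%). Stromal markers came to 1095 ± 15.7, 1349 ± 33 and 1090 ± 48.8 CPM, from Pecam1 (99.9%). None of these sums tells which cells made the transcripts, so it does not by itself show that such cells were present. Erythroid and megakaryocyte markers (42.1 ± 5.68, 26.7 ± 16.8 and 33.2 ± 2.16 CPM), eosinophil markers (6.03 ± 1.06, 4.06 ± 3.27 and 4.6 ± 1.13 CPM) and B cell markers (0.722 ± 0.046, 0.849 ± 0.48 and 0.74 ± 0.204 CPM) were scarce. The B cell and stromal lists, with 1 and 2 members tested, were not run in the camera test, and none of the other 7 lists beside NK identity passed it in any comparison. SIS3_TGFb replicate 3 stood apart from its group in macrophage markers (2183 CPM against 1334 and 1228 CPM) and dendritic cell markers (969 CPM against 618 and 573 CPM). TGFb replicate 3 was low in several mast cell, basophil and megakaryocyte transcripts. The basophil protease Prss34 stood at 3.46 CPM against 21 to 38.2 CPM in the other 8 libraries, and the transcription factor Gata2 at 0.466 CPM against 3.6 to 8.03 CPM. In that library Mcpt8 (233 CPM against 169 to 257 CPM) and Kit (229 CPM against 167 to 273 CPM) lay within the range of the other libraries. These 4 genes, and Itga2b and Ppbp in the figure, were chosen after their values were seen.

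**Figure D1:**
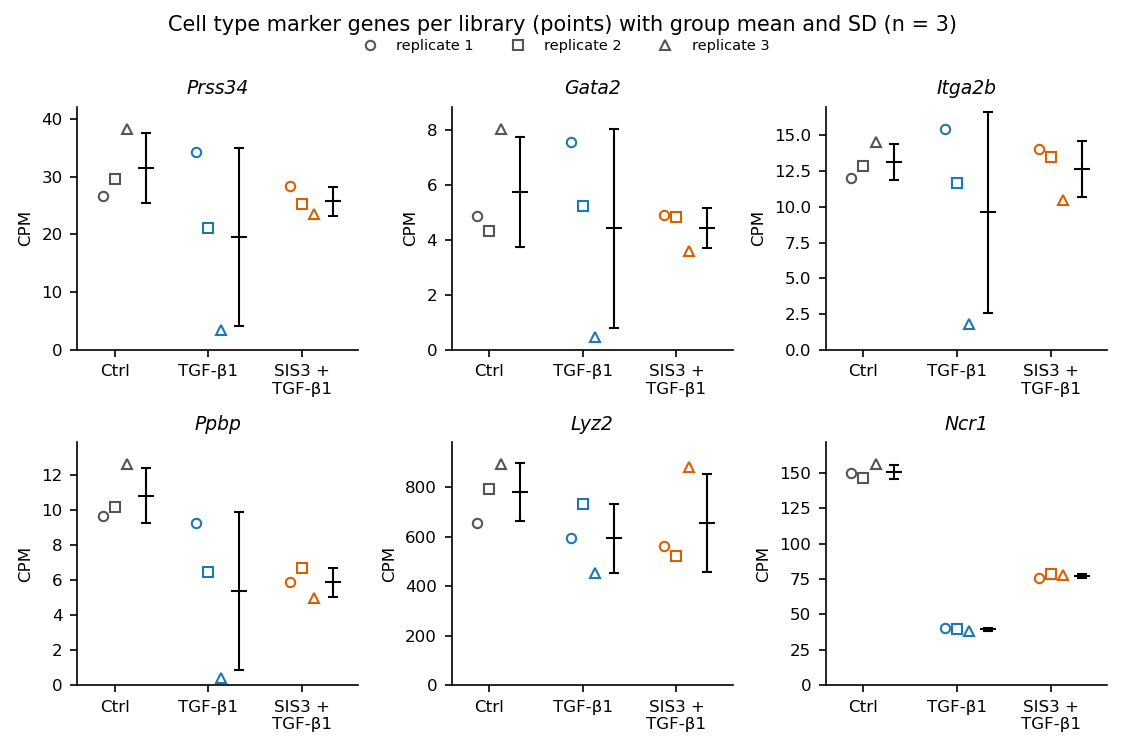
CPM of 6 marker genes of cell types in each of the 9 libraries (symbols mark the replicate number), with the mean and SD of each group (n = 3). All 6 were lowest in TGFb replicate 3, where Prss34 stood at 3.46 CPM and Lyz2 at 452 CPM (521 to 892 CPM in the other libraries). The NK receptor gene Ncr1 stood at 38.28 CPM there and was spread by 1.14 CPM (SD) in the TGFb group.

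TGFb versus Ctrl asked what 3 h of TGF-β1 changed. Pmepa1, a membrane protein that dampens TGF-β signalling (Entrez 65112, chromosome 2, 173224458 to 173276731 in GRCm38.p6), rose from 0.661 ± 0.205 to 137 ± 4.8 CPM, a log2 change of 7.69 ± 0.103 (n = 3 per group). Ncr1, which encodes the activating receptor NKp46 (Entrez 17086, chromosome 7, 4337715 to 4345184), fell from 151 ± 4.86 to 39.5 ± 1.14 CPM, a log2 change of -1.93 ± 0.042. Gzmb, the granule protease granzyme B, fell from 8278 ± 358 to 5622 ± 311 CPM (log2 -0.56 ± 0.046), and Prf1, the pore-forming perforin, fell by 0.36 (SE 0.048) on the log2 scale. Of 12212 genes tested, 4190 changed (34.3%), 2186 up and 2004 down, and 493 of these changed by a log2 of at least 1, 363 up and 130 down. The libraries of both groups did not overlap for 4057 of the changed genes and for 45% of all genes, where chance gives 10%. With upper-quartile factors the split was 1807 up and 2568 down, which puts the rises at 41.3% of the changed genes against 52.2% with TMM factors.

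Direct SMAD targets and feedback regulators of the pathway rose as a group. Of 26 tested, 18 rose, 3 fell and 5 did not pass, the same counts when adjusted over the list alone, with a median log2 change of 0.54 (camera adjusted p = 2.7e-23, and adjusted p = 0.001 with an estimated correlation). Besides Pmepa1, the repressors of SMAD activity Ski (3.07 ± 0.054), Skil (1.33 ± 0.048) and Smad7 (1.92 ± 0.102) rose. So did Ldlrad4 (2.98 ± 0.075), a further inhibitor of the pathway, while Id2, a regulator that NK cells need, fell (-0.42 ± 0.045). Among 18 components of the pathway 8 rose, 0 fell and 10 did not pass (8 and 1 adjusted over the list alone). The ligands Tgfb1 (1.19 ± 0.04) and Tgfb3 (3.68 ± 0.224) and the receptor Acvr1b (1.39 ± 0.116) were among those that rose. The test called this list up (adjusted p = 0.011, mean 0.48) although its median was -0.04, with adjusted p = 0.24 with an estimated correlation and 0.068 with limma voom. Smad3 itself rose from 4.3 ± 0.915 to 9.75 ± 0.591 CPM (1.18 ± 0.155) and the receptor Tgfbr1 by 0.27 ± 0.056.

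The other large rises were in genes of varied function. They included the sodium channel subunit Scn3b (5.89 ± 0.275, from 6 counts over the Ctrl libraries), Clmn (4.49 ± 0.444, from 5 counts) and Ndrg4 (4.37 ± 0.24). Others were the receptor for vasoactive intestinal peptide Vipr2 (4.14 ± 0.17), Gpr155 (3.93 ± 0.132), the imprinted gene Mest (3.91 ± 0.131) and the proton-sensing receptor Gpr4 (3.75 ± 0.289). Large falls beside Ncr1 were those of the transcription factor Irf4 (-2.09 ± 0.214), the iron exporter Slc40a1 (-2.04 ± 0.189), Fgd4 (-2.02 ± 0.256), Khdc1b (-1.96 ± 0.242), Ndnf (-1.92 ± 0.091), Prrg1 (-1.74 ± 0.233) and Filip1 (-1.63 ± 0.064). Ndrg1, a stress-responsive gene, fell from 61.1 ± 1.36 to 26.1 ± 1.31 CPM (-1.23 ± 0.065).

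Genes of NK cell recognition and killing shifted down. Their lists share members (Gzmb and Prf1 are both NK identity markers and cytotoxic effectors), so these tests are not independent in any comparison. Of 14 NK identity markers 8 fell, 0 rose and 6 did not pass, the same counts adjusted over the list alone (adjusted p = 1.9e-05, and adjusted p = 0.044 with an estimated correlation). Of 22 activating receptors and adaptors 10 fell, 0 rose and 12 did not pass, again the same adjusted over the list alone (adjusted p = 0.00034, but adjusted p = 0.056 with an estimated correlation). After Ncr1, the falls included Slamf7 (-0.67 ± 0.064) and Klrb1c (-0.31 ± 0.04), a C-type lectin-like receptor. Klrk1, which encodes the receptor NKG2D, fell by 0.21 (SE 0.058). Of 21 cytotoxic effectors 9 fell, 4 rose and 8 did not pass (10 and 4 adjusted over the list alone; adjusted p = 0.0098, but adjusted p = 0.38 with an estimated correlation). Serpinb9, an inhibitor of granzyme B, fell by 1.14 (SE 0.04), and Rab27a, which docks granules, rose by 0.41 ± 0.035. The cytokine Ifng fell from 7.73 ± 0.536 to 4.93 ± 0.623 CPM (-0.64 ± 0.131). The NK transcription factors Nfil3 (0.02 ± 0.038), Tbx21 (0.13 ± 0.064) and Eomes (-0.07 ± 0.032) did not pass the test, although Eomes passed it with upper-quartile factors (adjusted p = 0.013) and without scaling factors (adjusted p = 0.029). The cytokine Csf2 was filtered out, with 0 to 12 expected counts per library.

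Mitotic, replication and MYC genes mostly fell, and stress genes went both ways. A further proliferation list, the G1 cyclins and cell cycle inhibitors, did not pass (6 fell, 3 rose and 6 did not pass of 15, camera adjusted p = 0.15). Of 30 G2/M genes 26 fell, 0 rose and 4 did not pass (28 fell adjusted over the list alone; adjusted p = 6.6e-05, but adjusted p = 0.52 with an estimated correlation). The centromere gene Cenpa (-0.68 ± 0.059) and the cyclin Ccna2 (-0.52 ± 0.065) were among those that fell. Of 30 DNA replication and G1/S genes 18 fell, 0 rose and 12 did not pass (22 adjusted over the list alone; adjusted p = 0.0018, but adjusted p = 0.38 with an estimated correlation). The helicase subunit Mcm6 stood at -0.34 ± 0.037. Of 30 MYC and ribosome biogenesis genes 22 fell, 4 rose and 4 did not pass, the same adjusted over the list alone (adjusted p = 5.4e-06, but adjusted p = 0.17 with an estimated correlation). Among them were Myc at -0.97 ± 0.058, Mycn at -1.39 ± 0.127 and the pyrimidine synthesis enzyme Cad at 1.08 ± 0.048. Of 16 heat shock genes 9 fell, 1 rose and 6 did not pass, the same adjusted over the list alone (adjusted p = 0.0018, but adjusted p = 0.085 with an estimated correlation), led by the chaperone Hsph1 (-0.66 ± 0.048). Of 24 p53 targets 10 rose, 3 fell and 11 did not pass, the same adjusted over the list alone (adjusted p = 0.041, but adjusted p = 0.24 with an estimated correlation). The nuclease Aen (0.79 ± 0.044) and the DNA repair gene Xpc (0.93 ± 0.065) rose. This call ended with upper-quartile factors (adjusted p = 0.053), without Ctrl replicate 1 (0.052) and without TGFb replicate 2 (0.058). Of the 41 lists 10 passed, but wrong groupings of the same 6 libraries called up to 22. Members of lists that did not pass also changed. The chemokine receptor Ccr2 (-1.52 ± 0.058) fell and Gpr183 (2.33 ± 0.137) rose. Of the 14 genes of that list 4 rose, 3 fell and 7 did not pass, the same adjusted over the list alone. The test pointed down (adjusted p = 0.24) although the median was 0.28 and the mean 0.2. Of 23 tissue residency genes 10 rose, 5 fell and 8 did not pass (10 and 6 adjusted over the list alone; adjusted p = 0.13). Examples were the ectoenzyme Nt5e at 2.5 ± 0.136 and the inhibitory receptor Ctla4 at -1.26 ± 0.076. Of 29 NK transcription factors 6 rose, 10 fell and 13 did not pass (6 and 11 adjusted over the list alone; adjusted p = 0.29). Among them were Runx3 at 0.84 ± 0.047 and Prdm1 at -1.03 ± 0.061.

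**Figure D2:**
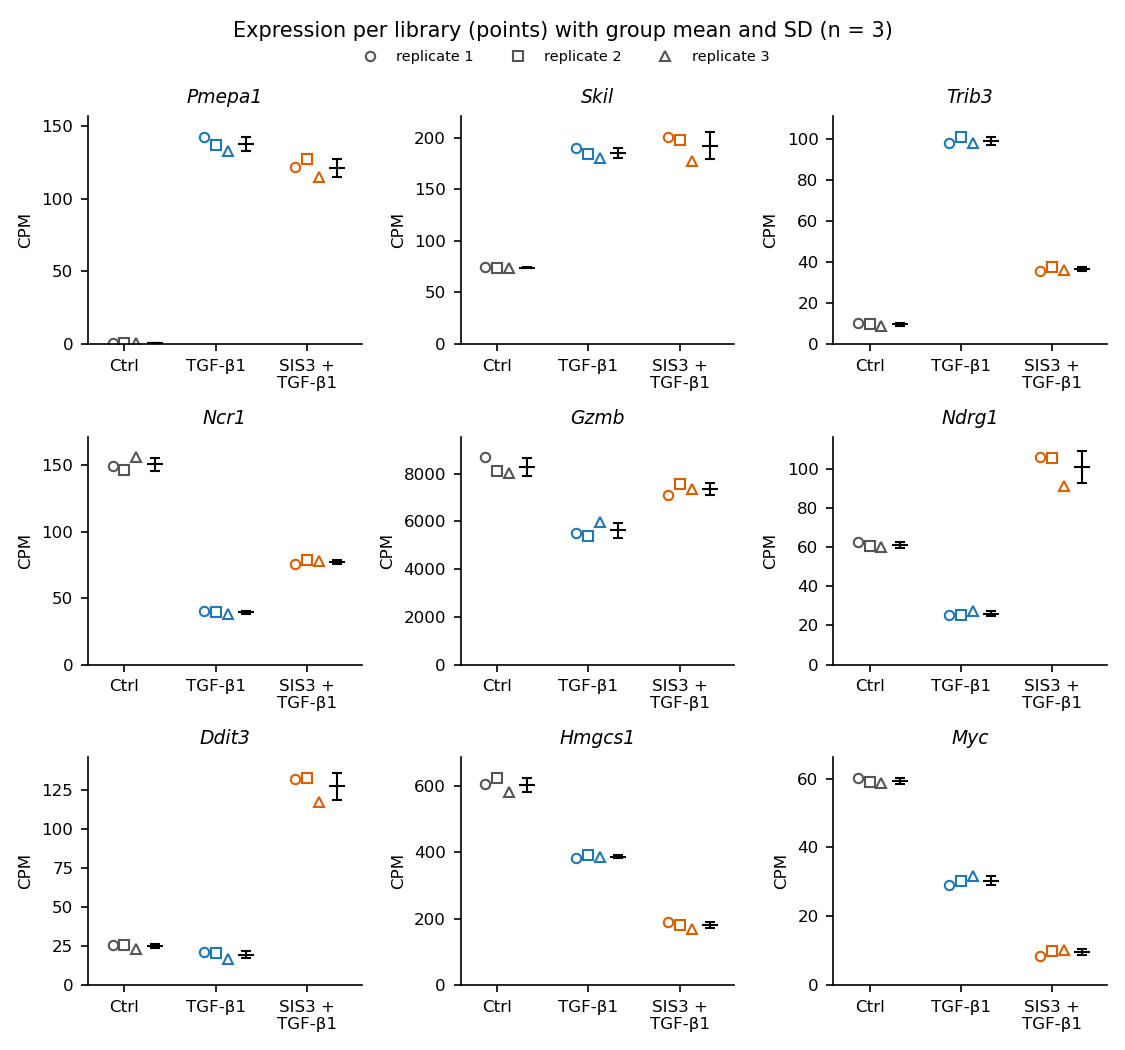
CPM of 9 genes in each of the 9 libraries (symbols mark the replicate number), with the mean and SD of each group (n = 3). Pmepa1 stood at 137 CPM in TGFb and 121 CPM in SIS3_TGFb against 0.661 CPM in Ctrl, Ncr1 at 39.5 and 77.4 CPM against 151 CPM, and Ddit3 at 127 CPM in SIS3_TGFb against 19.4 CPM in TGFb.

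SIS3_TGFb versus TGFb asked what SIS3 changed in cells that all received TGF-β1. Ddit3, the stress transcription factor CHOP (Entrez 13198, chromosome 10, 127290793 to 127296291), rose from 19.4 ± 2.23 to 127 ± 8.56 CPM (log2 2.71 ± 0.072, n = 3 per group). Ndrg1 rose from 26.1 ± 1.31 to 101 ± 8.33 CPM (1.95 ± 0.063), above its Ctrl level, and Ncr1 from 39.5 ± 1.14 to 77.4 ± 1.4 CPM (0.97 ± 0.044). The growth regulator Myc (Entrez 17869, chromosome 15, 61985341 to 61990361) fell from 30.4 ± 1.38 to 9.55 ± 0.864 CPM (-1.67 ± 0.072). In all, 5104 genes changed (41.8%), 2585 up and 2519 down, and 283 changed by a log2 of at least 1, 241 up and 42 down. The libraries did not overlap for 4942 of the changed genes and for 51.4% of all genes, where chance gives 10%. Without scaling factors the split was 3690 up and 1501 down (71.1% up against 50.6%).

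The SMAD targets were not told apart from other genes as a group in this step. Of 26 tested 10 rose, 6 fell and 10 did not pass, the same adjusted over the list alone (median 0.13, adjusted p = 0.63). Against no change, rather than against other genes, the list passed upwards in the fry test (adjusted p = 0.00071). Klf10 (1.12 ± 0.089) and the cell cycle inhibitor Cdkn1a (0.44 ± 0.035) rose, and Junb (-0.41 ± 0.047) and Ski (-0.34 ± 0.044) fell. Pmepa1 fell from 137 to 121 ± 6.19 CPM (-0.18 ± 0.047), a call that ended without scaling factors (adjusted p = 0.11). Skil was at 0.05 ± 0.044 and did not pass, although it passed without SIS3_TGFb replicate 3 (adjusted p = 0.031) and without scaling factors (adjusted p = 0.019). Smad7 rose by 0.25 ± 0.082, a call that ended without TGFb replicate 1 (adjusted p = 0.1), without SIS3_TGFb replicate 1 (0.099), without SIS3_TGFb replicate 2 (0.079) and in DESeq2 (0.076). Smad3 fell from 9.75 to 5.61 ± 0.824 CPM (-0.8 ± 0.148). Tgfbr1 fell by 0.16 (SE 0.055), which ended without TGFb replicate 2 (adjusted p = 0.1), without TGFb replicate 3 (0.066), without SIS3_TGFb replicate 1 (0.056), without SIS3_TGFb replicate 2 (0.12), in DESeq2 (0.074) and without scaling factors (0.34).

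Genes of the ATF4 and amino acid stress response rose together. Of 34 tested 32 rose, 2 fell and 0 did not pass, the same adjusted over the list alone, with a median log2 change of 0.91 (adjusted p = 2.1e-76, and adjusted p = 0.00011 with an estimated correlation). Besides Ddit3, the amino acid transporter subunits Slc7a5 (1.27 ± 0.037) and Slc3a2 (1.19 ± 0.038) rose. The members that fell were Trib3, a pseudokinase induced by the pathway (-1.44 ± 0.046), and Chac1, which breaks down glutathione (-1.26 ± 0.11), both of which had risen with TGF-β1 (3.37 ± 0.057 and 1.48 ± 0.114). Of 22 unfolded protein response genes 7 rose, 5 fell and 10 did not pass, the same adjusted over the list alone. Members included Herpud1 at 1.88 ± 0.048, Xbp1 at 0.76 ± 0.04 and the chaperone Hspa5 at 0.42 ± 0.038. That list was called up (adjusted p = 0.025, median 0.02), a call that ended with an estimated correlation (adjusted p = 0.4), limma voom (0.46) and without TGFb replicate 1 (0.07). Of 24 p53 targets 11 rose, 1 fell and 12 did not pass (13 and 1 adjusted over the list alone; adjusted p = 0.0061, but adjusted p = 0.2 with an estimated correlation). Examples were Sesn2 at 0.93 ± 0.064 and the cell death gene Bbc3 at 0.83 ± 0.06. Of 5 metallothionein and MTF1 genes 3 rose, 0 fell and 2 did not pass, the same adjusted over the list alone (adjusted p = 0.0061, but adjusted p = 0.2 with an estimated correlation and 0.094 with limma voom). Those that rose were the metal binders Mt2 (1.11 ± 0.067) and Mt1 (0.61 ± 0.075) and the zinc exporter Slc30a1 (1.44 ± 0.147). Further large rises were those of Ciart, a repressor of the circadian clock (3.35 ± 0.138), the stress gene Nupr1 (2.9 ± 0.133) and Csprs (2.88 ± 0.288). They also took in Extl1 (2.65 ± 0.108), the ephrin Efnb2 (2.44 ± 0.188), Arrdc3 (2.32 ± 0.086) and the fatty acid elongase Elovl7 (2.29 ± 0.193).

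Genes of lipid and sugar metabolism fell. Of 28 cholesterol synthesis genes and SREBP2 targets 24 fell, 2 rose and 2 did not pass, the same adjusted over the list alone (adjusted p = 3.5e-13, but adjusted p = 0.2 with an estimated correlation). The synthase Hmgcs1 (-1.1 ± 0.042) and the fatty acid synthase Fasn (-1.11 ± 0.061) fell, and Tmem97 (0.38 ± 0.065) rose. Of 21 glycolysis genes 16 fell, 1 rose and 4 did not pass, the same adjusted over the list alone (adjusted p = 0.00037, but adjusted p = 0.4 with an estimated correlation). The hexokinase Hk1 (-0.49 ± 0.039) and the pyruvate kinase Pkm (-0.36 ± 0.045) fell, and the regulatory enzyme Pfkfb3 (0.52 ± 0.047) rose.

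Cytotoxic effector genes mostly fell, more cytokine-signalling and adhesion genes fell than rose, and mitotic genes mostly rose. Of 21 cytotoxic effectors 14 fell, 2 rose and 5 did not pass (15 and 2 adjusted over the list alone; adjusted p = 0.00077, but adjusted p = 0.32 with an estimated correlation). Gzmb rose by 0.39 ± 0.046 to 7353 ± 237 CPM, Gzme (-0.81 ± 0.058) and Gzmd (-0.45 ± 0.048) fell, and Prf1 (-0.08 ± 0.048) did not pass. Ifng rose by 0.57 ± 0.131 to 7.34 ± 0.474 CPM, Tbx21 rose by 0.26 ± 0.062 and Eomes fell from 517 ± 2.61 to 367 ± 7.14 CPM (-0.49 ± 0.033). Nfil3 (0.07 ± 0.038) did not pass, except without TGFb replicate 3 (adjusted p = 0.029), without that library and SIS3_TGFb replicate 3 (0.024) and without scaling factors (0.0015). Klrk1 rose by 0.2 ± 0.058, a call that ended without TGFb replicate 3 (adjusted p = 0.058) and without SIS3_TGFb replicate 1 (0.08). Of 28 genes of IL-2 and IL-15 signalling through STAT5 11 fell, 5 rose and 12 did not pass (11 and 6 adjusted over the list alone). The feedback inhibitor Cish (-0.96 ± 0.062) and the receptor Il2ra (-0.56 ± 0.041) fell. Its call (adjusted p = 0.032) ended with an estimated correlation (adjusted p = 0.32), limma voom (0.23) and library totals alone (0.074), where the median turned from -0.06 to 0.03. Of 25 immediate early genes 13 fell, 5 rose and 7 did not pass (13 and 6 adjusted over the list alone; adjusted p = 0.0061, but adjusted p = 0.32 with an estimated correlation). Examples were the nuclear receptor Nr4a2 at -1.47 ± 0.089 and the signalling inhibitor Spry2 at -1.07 ± 0.055. Of 24 adhesion and cytoskeleton genes 11 fell, 1 rose and 12 did not pass, the same adjusted over the list alone (adjusted p = 0.0044, but adjusted p = 0.37 with an estimated correlation). The integrin Itgb2 stood at -0.48 ± 0.036. Of 21 NF-κB targets 8 rose, 3 fell and 10 did not pass (10 and 3 adjusted over the list alone; adjusted p = 0.021, but adjusted p = 0.2 with an estimated correlation and 0.061 without TGFb replicate 3 and SIS3_TGFb replicate 3). The inhibitor Tnfaip3 stood at 0.65 ± 0.058. Of 30 G2/M genes 23 rose, 0 fell and 7 did not pass (25 rose adjusted over the list alone; adjusted p = 0.0012, but adjusted p = 0.67 with an estimated correlation). The motor protein Kif11 stood at 0.51 ± 0.072. Further large falls were those of the zinc importer Slc39a10 (-1.31 ± 0.14), the calcium-binding S100a11 (-1.25 ± 0.04), the splicing regulator Esrp2 (-1.23 ± 0.241) and Klhl30 (-1.11 ± 0.057). Of the 41 lists 12 passed, but wrong groupings of the same 6 libraries called up to 17.

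**Figure D3:**
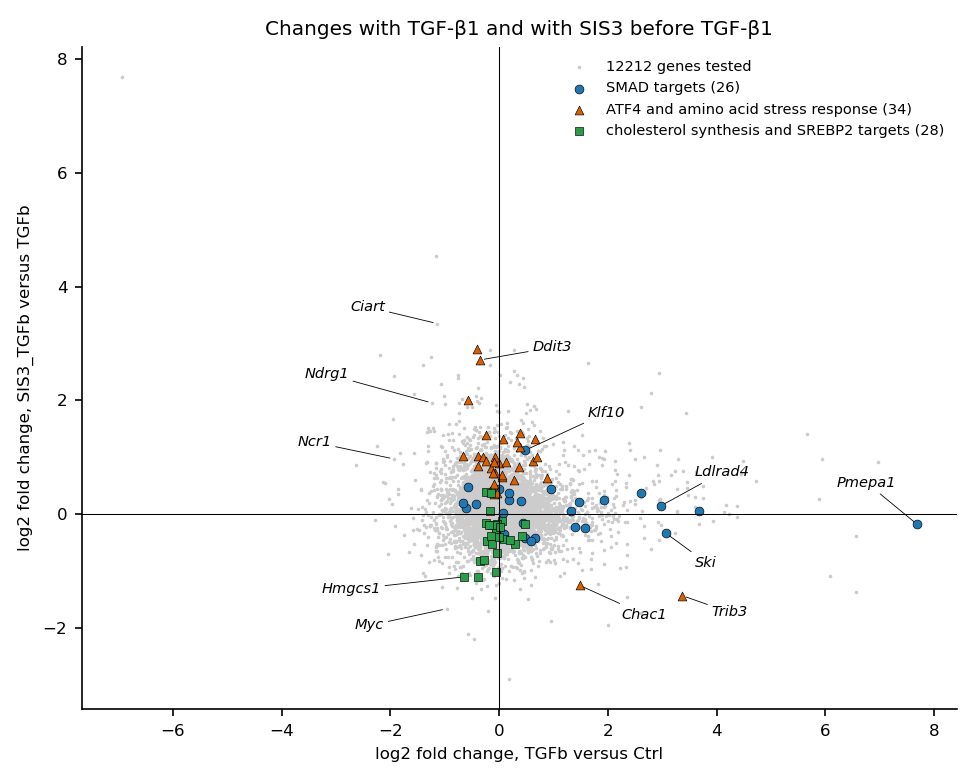
Log2 fold change of TGFb versus Ctrl (horizontal) against SIS3_TGFb versus TGFb (vertical) for the 12212 genes tested, with the SMAD targets, the ATF4 response and the cholesterol genes marked. Both axes share the TGFb libraries, so chance spread alone slopes downwards; 18 of the 26 SMAD targets rose with TGF-β1, 3 fell, and the vertical median of the 26 was 0.13, and 32 of the 34 ATF4 genes lie above 0.

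SIS3_TGFb versus Ctrl gave the net change with both treatments. Pmepa1 stood at 121 ± 6.19 against 0.661 ± 0.205 CPM (log2 7.5 ± 0.105, n = 3 per group). Ncr1 stood at 77.4 ± 1.4 against 151 ± 4.86 CPM (-0.96 ± 0.039) and Myc at 9.55 ± 0.864 against 59.3 ± 0.793 CPM (-2.63 ± 0.067). Of the genes tested, 6585 changed (53.9%), 3542 up and 3043 down, and 886 changed by a log2 of at least 1, 664 up and 222 down. The libraries did not overlap for 6397 of the changed genes and for 61.1% of all genes, where chance gives 10%. Without scaling factors the split was 4222 up and 2395 down (63.8% up against 53.8%).

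SMAD targets remained high. Of 26 tested 17 rose, 2 fell and 7 did not pass, the same adjusted over the list alone (median 0.59, adjusted p = 5.2e-17, and adjusted p = 0.0014 with an estimated correlation). Among them were Ski at 2.73 ± 0.054, Skil at 1.38 ± 0.047, Ldlrad4 at 3.13 ± 0.074 and Smad7 at 2.17 ± 0.1. Of the 18 targets that rose with TGF-β1, 16 were also above Ctrl with SIS3, 8 rose further in the second step, 5 fell back and 5 did not pass there. Of 18 pathway components 8 rose, 1 fell and 9 did not pass, the same adjusted over the list alone (adjusted p = 0.017, but adjusted p = 0.17 with an estimated correlation). Tgfb1 stood at 1.16 ± 0.04. Smad3 was at 0.39 ± 0.164 and Tgfbr1 at 0.11 ± 0.056, and neither passed. Smad3 passed without Ctrl replicate 1 (adjusted p = 0.017), without SIS3_TGFb replicate 2 (0.04) and without scaling factors (0.031), and Tgfbr1 passed with the macrophage covariate (adjusted p = 0.039) and without scaling factors (0.021). The large rises were those of Scn3b (6.14 ± 0.266), Clmn (5.42 ± 0.392), Wscd1 (5.21 ± 0.278), Mest (4.92 ± 0.117), Ndrg4 (4.51 ± 0.235), Gpr4 (4.23 ± 0.272) and Vipr2 (4.17 ± 0.169). Among large falls were Slc40a1 (-2.75 ± 0.202), Mycn (-2.42 ± 0.14), the RNA-binding Celf4 (-2.13 ± 0.209), Ndnf (-2.13 ± 0.092), Prrg1 (-2.1 ± 0.24), the kinase Alpk2 (-2 ± 0.1) and Nr4a2 (-1.97 ± 0.086).

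NK effector genes were lower than in Ctrl. Of 22 activating receptors and adaptors 13 fell, 1 rose and 8 did not pass, the same adjusted over the list alone (adjusted p = 9.8e-05, and adjusted p = 0.044 with an estimated correlation). Examples were Slamf7 at -1.59 ± 0.068 and Klrd1 at -0.81 ± 0.048. Of 21 cytotoxic effectors 15 fell, 1 rose and 5 did not pass, the same adjusted over the list alone (adjusted p = 3.5e-06, but adjusted p = 0.1 with an estimated correlation). Among them were Serpinb9 at -1.43 ± 0.041, Prf1 at -0.43 ± 0.048 and Gzmb at -0.17 ± 0.046. NK identity markers (2 rose, 7 fell, 5 did not pass, the same adjusted over the list alone) had adjusted p = 0.007, but adjusted p = 0.094 with an estimated correlation. The genes of circulating NK cell maturation (2 rose, 7 fell, 5 did not pass of 14, the same adjusted over the list alone) had adjusted p = 0.0055, but adjusted p = 0.094 with an estimated correlation. Members included Prdm1 at -1.4 ± 0.062, Eomes at -0.57 ± 0.033 and Tbx21 at 0.39 ± 0.062. Inhibitory receptors (3 rose, 11 fell, 6 did not pass of 20, the same adjusted over the list alone) had adjusted p = 0.039, which ended with an estimated correlation (adjusted p = 0.36) and without Ctrl replicate 2 (0.058). The checkpoint receptor Havcr2 stood at -1.02 ± 0.043. Ndrg1 rose by 0.72 ± 0.056, and Ifng (-0.08 ± 0.123), Klrk1 (-0.02 ± 0.057) and Nfil3 (0.09 ± 0.038) did not pass. Nfil3 passed without TGFb replicate 3 (adjusted p = 0.033), without that library and SIS3_TGFb replicate 3 (0.029) and without scaling factors (0.0013).

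The ATF4 list was above Ctrl as well, with 32 of 34 risen, 0 fallen and 2 not past the test, the same adjusted over the list alone (median 0.88, adjusted p = 2.8e-39, and adjusted p = 0.00043 with an estimated correlation). Examples were Slc7a5 at 1.59 ± 0.037 and Ddit3 at 2.36 ± 0.07. Of 24 p53 targets 14 rose, 0 fell and 10 did not pass, the same adjusted over the list alone (adjusted p = 0.00017, and adjusted p = 0.049 with an estimated correlation). Sesn2 stood at 1.55 ± 0.066. Of 16 heat shock genes 13 fell, 1 rose and 2 did not pass, the same adjusted over the list alone (adjusted p = 0.00019, and adjusted p = 0.047 with an estimated correlation). Bag3 stood at -0.71 ± 0.06. NF-κB targets (16 rose, 2 fell, 3 did not pass, the same adjusted over the list alone) had adjusted p = 0.0047, but adjusted p = 0.094 with an estimated correlation. Relb stood at 1.07 ± 0.056. Cholesterol genes (22 fell, 2 rose, 4 did not pass; 22 and 3 adjusted over the list alone) had adjusted p = 1.1e-09, but adjusted p = 0.14 with an estimated correlation. Hmgcs1 stood at -1.75 ± 0.042. Glycolysis genes (17 fell, 1 rose, 3 did not pass, the same adjusted over the list alone) had adjusted p = 5.4e-05, but adjusted p = 0.29 with an estimated correlation. The glucose transporter Slc2a3 stood at -1.15 ± 0.041. MYC and ribosome biogenesis genes (22 fell, 4 rose, 4 did not pass, the same adjusted over the list alone) had adjusted p = 3.5e-06, but adjusted p = 0.094 with an estimated correlation. Dkc1 stood at -1.05 ± 0.059. DNA replication genes (18 fell, 3 rose, 9 did not pass; 19 and 3 adjusted over the list alone) had adjusted p = 0.0046, but adjusted p = 0.43 with an estimated correlation. The sliding clamp Pcna stood at -0.61 ± 0.038. IL-2 and IL-15 signalling genes (15 fell, 5 rose, 8 did not pass, the same adjusted over the list alone) had adjusted p = 0.0047, but adjusted p = 0.11 with an estimated correlation. Pim2 stood at -1.08 ± 0.074. The G2/M genes did not pass (1 rose, 6 fell, 23 did not pass; 0 and 5 adjusted over the list alone; adjusted p = 0.44), and 16 lists passed in all.

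**Figure D4:**
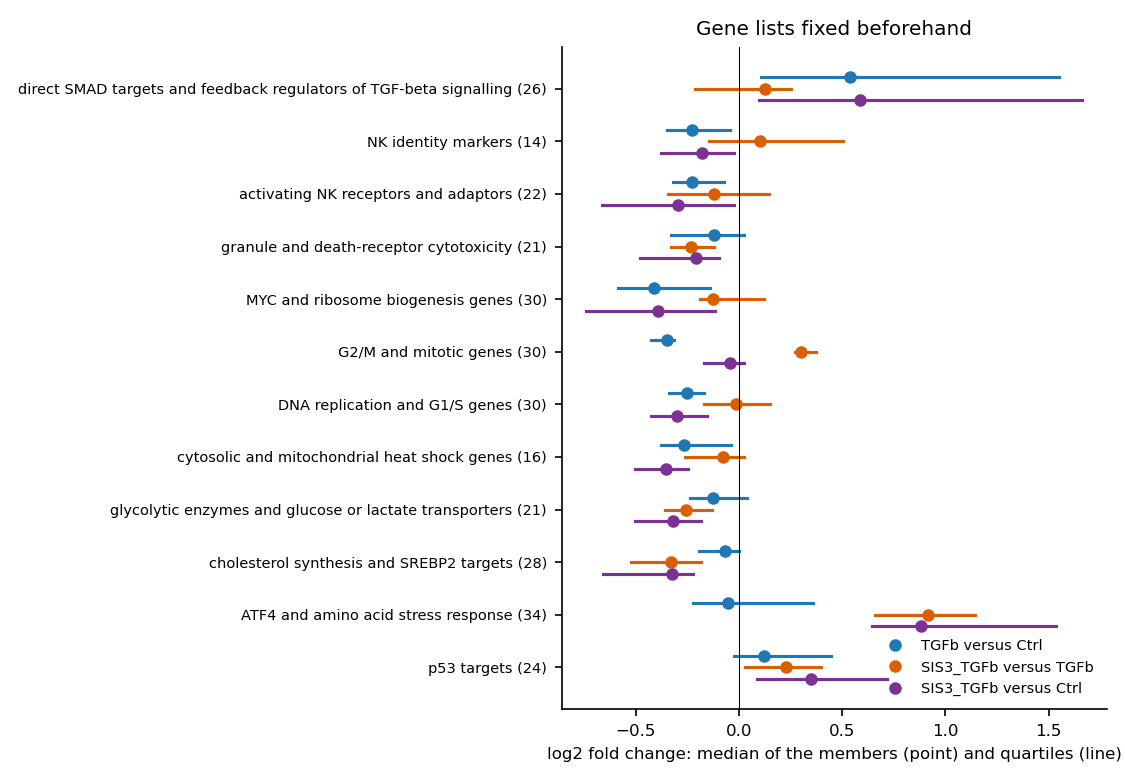
Median (point) and quartiles (line) of the log2 fold changes of the tested members of 12 lists in the 3 comparisons, with the number of members in brackets. The SMAD targets had medians of 0.54 in TGFb versus Ctrl and 0.59 in SIS3_TGFb versus Ctrl, and the ATF4 list had medians of 0.91 and 0.88 in the comparisons with SIS3.

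Whether SIS3 moved the genes that TGF-β1 had changed back towards Ctrl was asked of the 4190 genes changed by TGF-β1. Among the genes with the largest summed changes, Trib3 (Entrez 228775, chromosome 2, 152337425 to 152344060) rose from 9.57 ± 0.561 to 98.9 ± 1.86 CPM and fell back to 36.6 ± 1.03 CPM with SIS3 (n = 3 per group). Ciart fell from 6.52 ± 0.91 to 2.96 ± 0.245 CPM and rose to 30.2 ± 4.43 CPM. Clmn (2.48 ± 0.26 to 4.71 ± 0.875 CPM) and Wscd1 (2.32 ± 0.526 to 7.91 ± 0.643 CPM) rose further with SIS3. In all, 1188 genes moved back (28.4%), 993 moved further the same way (23.7%) and 2009 did not pass in the second step (47.9%). Of those that moved back, 617 did not pass against Ctrl, 329 were still changed in the direction of TGF-β1 and 242 had gone past Ctrl to the other side. Against Ctrl, 3019 of the 4190 genes (72.1%) changed in the same direction with SIS3, as did 446 of the 493 genes changed by a log2 of at least 1. Of those 493, 97 moved back, 34 of them by 50 percent or more, and the median share of the change that remained was 101.1%, both on the log2 scale. A further 2923 genes changed in the second step alone.

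More genes were shared by the steps than independent lists would share in each direction. Against 450.9 expected, 637 rose and then fell, and against 424.2 expected, 551 fell and then rose. There were 483 that rose in both steps against 462.7 and 510 that fell in both against 413.4. Simulated unchanged groups gave a mean of 0.05 genes moved back (0 to 1 over 20 simulations). They hold no changed gene, so they do not show how many changed genes move back through the shared TGFb libraries. The covariance of both steps over all genes was -0.0129 against -0.0146 in the simulations (-0.0162 to -0.0134). Over the 7363 genes of at least 4 log2 CPM, a limit chosen after the data were seen, it was -0.0032 against -0.0024 (-0.0027 to -0.0023). With 3 TGFb libraries they could not be parted into sets of at least 2 to free both steps of shared libraries. Among the genes moved back that the rule named, several rested on few counts. Moap1 was at 0 in the TGFb libraries and also in 1 Ctrl library. Over the summed counts of each group, TGFb was at least 14.7-fold lower than Ctrl and at least 24.7-fold lower than SIS3_TGFb. The change against Ctrl did not pass without Ctrl replicate 1 (adjusted p = 0.072) or with limma voom (0.059). Csdc2 was at 0 in Ctrl and at least 11.5-fold higher in TGFb, and Ccdc74a was 92.6-fold higher (16.2 to 3700) from 1 count in Ctrl. Prickle1 (-2.18 ± 0.746 and then 2.79 ± 0.679) and Ptx3 (2.62 ± 0.576 and then -1.75 ± 0.496) were under 1 CPM in every group. The call of Prickle1 in TGFb versus Ctrl ended without Ctrl replicate 1 (adjusted p = 0.052), Ctrl replicate 3 (0.2), TGFb replicate 1 (0.055), TGFb replicate 2 (0.051) or TGFb replicate 3 (0.089). That of Csdc2 in the second step ended without TGFb replicate 1 (0.052), SIS3_TGFb replicate 1 (0.066) or SIS3_TGFb replicate 3 (0.062). Of the genes moved further, Sertad4, Nxph4 and Duoxa1 were at 0 in Ctrl and at least 15.3-fold, 6.11-fold and 7.47-fold higher in TGFb. Their calls in the second step ended in DESeq2 (adjusted p = 0.15, 0.1 and 0.27). That of Sertad4 also ended without TGFb replicate 1 (0.14) or replicate 2 (0.089) and without SIS3_TGFb replicate 1 (0.075) or replicate 2 (0.1). That of Nxph4 ended without TGFb replicate 2 (0.065) or replicate 3 (0.056) and without SIS3_TGFb replicate 2 (0.063). That of Duoxa1 ended without each library in turn (0.051 to 0.17) except TGFb replicate 2.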

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

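The alternatives with library totals alone, without both TGFb replicate 3 and SIS3_TGFb replicate 3 and with the macrophage covariate were chosen after the data were seen. Leaving out each library in turn gave 3571 to 4297 changed genes in TGFb versus Ctrl (1908 to 2230 up, 1663 to 2067 down), 4295 to 5080 in SIS3_TGFb versus TGFb (2131 to 2562 up, 2164 to 2518 down) and 5875 to 6868 in SIS3_TGFb versus Ctrl (3151 to 3649 up, 2724 to 3219 down). It gave 10 to 12, 12 to 13 and 16 to 19 lists, 995 to 1109 genes moved back and 743 to 967 moved further. At a log2 size of at least 1, 493 (363 up, 130 down), 283 (241 up, 42 down) and 886 (664 up, 222 down) genes passed, 20 moved back and 17 moved further, since fewer genes reach that size. With an estimated correlation 2, 1 and 5 lists passed; the cause was not tested. The fry test against no change called 25, 23 and 24 of the 41 lists, among them the 10, 12 and 16 called by camera. Without the low-count filter 19 lists passed in TGFb versus Ctrl, and the cause was not tested. Without scaling factors 1501 genes fell in SIS3_TGFb versus TGFb. The TMM factors were 0.956 to 0.986 in TGFb and 1.026 to 1.046 in SIS3_TGFb. Leaving these out moved the median log2 change of all genes from 0.012 to 0.095, so fewer genes counted as fallen. DESeq2 called 3413, 4080 and 5630 genes and limma voom 4187, 5110 and 6592. Without TGFb replicate 3 and SIS3_TGFb replicate 3 there were 4230, 4738 and 6744, and with the macrophage covariate 3925, 5613 and 6338. Replicate number as a block gave 3942, 4803 and 6346. Same-number libraries of different groups correlated at -0.34 to 0.26 over 9 pairs, 2 of them above 0.1. Pairs with different numbers ran from -0.39 to 0.43. The numbers thus gave no sign of pairing, but with 3 libraries per group a shared mouse or culture is not excluded. Of 13696 combinations of a named gene, a comparison and an alternative, 13274 stayed as they were, passed or not passed. In 314 the call was lost, in 107 one was gained and 1 reversed. Signs were compared only where the gene passed in the main fit or in the alternative. The reversal was that of Cd74 in TGFb versus Ctrl, a gene of antigen-presenting cells, at 0.16 with the macrophage covariate. Its cause was not tested. The DESeq2 test gives no count of lists and the fit of the 6 compared samples alone no count of genes moved back or further. No scaling moved the median of all genes by 0.1 or more. Genes with few counts set the limit of depth: Csf2, at 0 to 12 counts per library, was not tested.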

Other observations

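The tests of other splits of the libraries were chosen after the results were seen, except that for the genes moved back. Also chosen after the result was seen were the 3 tests on the SMAD targets, the macrophage and the Ctrl-level tests on the ATF4 genes, and the macrophage marker test on TGFb replicate 3. The test on further markers of that library was planned before, but 2 of its genes (Osm and Itgb3), found in other fixed lists, were left out after a first value had been seen. The gene families and single genes of the next paragraph were chosen after their values were seen.

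The Gimap genes, GTPases of lymphocyte survival, fell with TGF-β1 in 8 of 8 members tested (median log2 -0.49, n = 3 per group) and fell again with SIS3 in 6 of 8 (median -0.28), which left 8 of 8 below Ctrl (median -0.76). Gimap7 fell by 1.17 (SE 0.073) with TGF-β1 and stood at -1.73 ± 0.077 against Ctrl with SIS3, and Gimap6 stood at -1.23 ± 0.04. Linker histone genes rose in SIS3_TGFb versus TGFb in 4 of 4 members tested (median 1.33), with H1f0 at 1.47 ± 0.046 and H1f2 at 0.97 ± 0.053. Of 13 hosts of small nucleolar RNAs (the Snhg genes and Gas5), 5 rose and 1 fell in that step, with Snhg5 at 1.91 ± 0.063, Snhg1 at 1.56 ± 0.077, Snhg12 at 1.53 ± 0.102 and Gas5 at -0.19 ± 0.07.

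The 6 libraries of each comparison have 10 splits, the real one included, too few for a share under 0.05. The real split called 4190 genes in TGFb versus Ctrl against at most 2 in any other (1 of 10 splits as large), 5104 against 0 in SIS3_TGFb versus TGFb (1 of 10) and 6585 against 0 in SIS3_TGFb versus Ctrl (1 of 10). For the lists the real splits called 10, 12 and 16, the highest of the others 22, 17 and 15, and 9, 6 and 1 of the 10 splits called as many. In TGFb versus Ctrl and SIS3_TGFb versus TGFb the number of lists called therefore did not stand out from that of wrong splits. For the genes moved back, 100 of 840 splits of the 9 libraries were drawn. Of these, 5, the real one included, gave at least the real 1188, with 2307 as the highest, so this count of splits does not exclude chance. The simulated unchanged groups (mean 0.05, 0 to 1 over 20 simulations) hold no changed gene and cannot settle it either. The 4 other splits this large gave 1949 to 2307 genes, and each kept the libraries of Ctrl or of SIS3_TGFb together as the middle group against mixtures of the other groups, which points to the structure of the 3 groups, so that these splits carry real group differences. The drawn splits that kept the TGFb libraries as the middle group gave 62 and 60.

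SMAD targets stayed above Ctrl with SIS3. A fall hidden by the choice among the 4 scalings is argued against by the second-step median of the 18 risen targets, 0.09 to 0.18. All 4 are relative to the other genes of a library, so they could not show a fall shared by all genes. Whether SIS3 removed 50 percent or more of the transcript response cannot be decided without a group given SIS3 alone. The net log2 change left had a median of 104.5% (quartiles 85.8% to 138.9%). It was lowest for Junb (14.3%) and Jund (19.6%) and highest for Klf10 (332.7%) and Cdkn2b (301.4%). A rise brought by SIS3, its solvent or the 3 h of incubation before TGF-β1 would count there as response left. Cells that SIS3 had not reached stay open. In SIS3_TGFb versus TGFb 283 genes were called at a log2 size of at least 1, against 0 in the other splits. Whether the TGFb cells received the solvent is not given in the sources used here, and no such incubation is listed for them. A solvent or incubation given to the SIS3_TGFb cells alone could give such a count. A dose too low to block Smad3 stays open too, since its phosphorylation was not measured.

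ATF4 genes rose in SIS3_TGFb versus TGFb. A trend with GC content, transcript length and expression level is argued against by a median residual of 0.96 (0.91 before), and a different share of macrophages by a median of 0.91 with their marker level as a covariate. An undoing of a fall brought by TGF-β1 is argued against by a median of 0.88 against Ctrl, where TGF-β1 alone gave -0.06. The response may therefore belong to SIS3, its solvent or the 3 h of incubation before TGF-β1, as a hypothesis. No such incubation without SIS3 is listed for the TGFb cells. Without a group given SIS3 alone, an effect of the compound and an effect that needs TGF-β1 stay open.

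TGFb replicate 3 was low in mast cell, basophil and megakaryocyte markers, by a median log2 of -2.28 over 17 genes against the other TGFb libraries. Its smaller depth is argued against by the totals, 15714973 expected counts against 16492031 and 16639359 in the other TGFb libraries. Thinning all libraries to the smallest total gave a median of -2.29. That step could change little, as the total was this library's own and CPM are scaled for depth. A larger share of NK cells that thins all other types alike is argued against by the macrophage markers, at a median of only -0.41. These markers were still low, with 17 of 19 below both other TGFb libraries. Of 14 NK identity markers 7 were below both (median -0.01). A smaller fall shared by cell types other than NK cells therefore stays open. Fewer cells of the basophil, mast cell, megakaryocyte and myeloid precursor lineages could account for part of it, as a hypothesis, since 13 further markers outside the fixed lists lay at a median of -1.23, with 11 below both other TGFb libraries. Against a loss of these lineages as a whole, the 5 basophil and mast cell genes among the 13 ranged from -2.18 to 0.23. The abundant Mcpt8 (233 CPM), Kit (229 CPM) and Cma1 (110 CPM) lay within the range of the other 8 libraries. Whether NK cells made Mcpt8, Kit and Cma1 was not measured, so these genes do not weigh against such a loss. T cell markers were low too (median -1.07 over 10 genes), which such a loss leaves unexplained. Their sum, mostly from Thy1, was not low (1960 CPM against 1814 and 1859 CPM in the other TGFb libraries). The design names no biological difference between this library and the other 2 of its group that could be tested.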
